A study of Arabidopsis thaliana with 8 samples.

How the data were processed

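Gene counts were analysed from RNA-seq of primary roots of Arabidopsis thaliana, accession Col-0. Each library came from a separate biological sample of about 70 seedlings. Seedlings grew at 21 °C on Murashige-Skoog medium without sucrose. In the dark groups the plates were wrapped in foil. In the lit-shoot groups a modified D-Root device, which shades the roots while the shoot stays lit, gave the shoots 16 h of light at 130 µmol and 8 h of dark per day. Roots were taken at 4 or 7 days. The 8 samples formed 4 groups of 2: dark at 4 days, dark at 7 days, lit shoots at 4 days and lit shoots at 7 days.

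The deposited table held whole-number counts per locus, made by the authors and not normalized. Per the labels, ribosomal RNA was depleted rather than poly(A) RNA selected, so that organelle transcripts stayed in the libraries and took a share of the counts. Per the submitters' processing notes, the tools were CASAVA 1.8.2, FastQC, Trim Galore, TopHat2 and Subread, and the build was TAIR10. Their settings, the strand used in counting and the treatment of reads with several matches are not given in the sources used here. Reads of near-identical copies could therefore be split or dropped, and reads of overlapping loci on opposite strands cannot be told apart. The 33602 loci were joined by their AGI identifiers to the TAIR10.1 gene table, which gave symbols and positions. Of these, 32835 loci were found and 10654 carried a symbol. The 279 organelle loci had no match there, so that the plastid-encoded and mitochondrion-encoded lists took all ATCG and ATMG loci, although their rule had asked for protein-coding loci.

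Library totals ran from 25326045 to 30555290 counts. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 20936. Counts were scaled with trimmed mean of M-values (TMM) factors, which ran from 0.912 to 1.088. All 8 samples entered one edgeR quasi-likelihood fit with a coefficient per group (glmQLFit with robust, glmQLFTest, 4 residual degrees of freedom) in R 4.3.3. The common biological coefficient of variation was 14.9%. The p-values were adjusted by Benjamini-Hochberg over the 20936 genes, and genes were called at an adjusted p below 0.05. An edgeR adjusted p below always means this test. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values (counts scaled to the library total times its TMM factor) are given as mean ± SD over n = 2 libraries. Where a group had no count, a lower bound of the fold was computed against a floor of 3 counts over the group. Where it had 1 to 3 counts, the 95% counting interval of the ratio is given, except for the interaction, which is not a ratio of 2 groups. Floors and intervals cover counting error only.

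The comparisons were lit shoots against dark at each day, 7 against 4 days within each condition, and the light by day interaction. The overlap of the light responses was tested with Fisher's exact test, two-sided. Organelle shares of counts were compared with exact permutation tests, two-sided. On counts simulated from these libraries for 20936 genes, of which 200 were changed, the test recovered 59.7% of the genes changed 2-fold and 89.4% of those changed 4-fold in the 4-day light comparison. The same shares were 59.7% and 81.8% for light at 7 days, 53.7% and 90.9% for time in the dark, 61.2% and 83.3% for time with lit shoots, and 14.9% and 71.2% for the interaction. Of the simulated calls, 10.3%, 5.6%, 11.4%, 10.3% and 9.5% were false in these comparisons. These shares hold for a setting with few changed genes and need not hold where many genes change.

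Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison that held at least 5 tested members. Camera was repeated with an estimated correlation, and fry was run as a companion. The 26 lists were light signalling, flavonoid biosynthesis, nuclear photosynthesis genes, chlorophyll biosynthesis, circadian clock, auxin, cytokinin, carbon starvation, sugar transport and cleavage, nitrogen, iron, cell cycle, root meristem and cap, root hair, xylem and secondary wall, Casparian strip and suberin, jasmonate, abscisic acid, heat shock proteins, glucosinolate, shoot tissue markers, seed storage, class III peroxidases, cytosolic ribosomal proteins, plastid-encoded and mitochondrion-encoded genes. The first 22 had named members, 448 in all. Of these, 438 carried their symbol in the reference, 1 was replaced by the locus that did (ZIP8), and 9 were dropped because no single locus did (UGT89C1, DVR, RVE6, PRODH2, BFRUCT3, BFRUCT4, FIT, IMA1 and HSP23.6).

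Genes are named by rule. In each comparison these were the 6 called genes with the largest rise and the 6 with the largest fall among genes with a symbol, an average log2 CPM of at least 2 and no overlap between the libraries of both groups. For the interaction they were 4 and 4 without the overlap condition. Each list added up to 3 called members with the smallest adjusted p, or its most abundant member where none was called, and 1 uncalled member at the highest level for lists that are described at length. The comparisons, tests, lists, this rule and the alternatives were fixed before the data were examined, except those the closing section says were added later.

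The alternatives were a replicate block, DESeq2 size factors, library totals without further scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 2 samples, removal of organelle, rRNA and tRNA loci, fits of only the 4 samples compared, an adjusted p of 0.01, a 2-fold minimum, and each library left out in turn. Exon length and GC content were removed as per-library trends in an alternative added later. Sequences of 221 genes were searched against all transcripts with blastn 2.17.0 (at least 95% identity over 100 bases): 7 had a copy, and 56 overlapped another locus. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.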

Results

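RNA-seq measured primary root transcripts of dark seedlings and of seedlings with lit shoots and shaded roots. Each of the 4 groups held 2 independent biological samples. Library totals were 26457216 and 25326045 counts for dark roots at 4 days and 26854333 and 27787166 for dark roots at 7 days. They were 28839293 and 27144399 for roots of lit shoots at 4 days and 25849135 and 30555290 for roots of lit shoots at 7 days. Replicate libraries correlated across genes at 0.98 to 0.987 (log2 CPM), and genes are not independent replicates. Their counts differed by more than sampling noise in every group, at chi-square over degrees of freedom of 12.2 to 68.7. Some values are uncertain because the strand and multiple matches in counting are not known. ABCC9 and ABCC15 are copies at 98.3% identity, CAB1 resembles CAB3 and CAB2 at 96.1%, and RPS28 shares a stretch with another locus. F3H, RPS2, LAC17, FER1, BOA, AK3, SYP111 and RRTF1 overlap a locus on the opposite strand over 94.5% to 21.7% of their length. CKX5, BGAL4, SRO3, PCNA2, BCAT4, LHB1B2, AIL6, CAB1, CRD1 and FLA11 do so over 17% to 6.2%, and TT4, XCP1, ABCC9, THA1, ICS2, MGL, BCE2, ASN1, CASP5, RHM1, RPL3B, RPS28, HSP101, LHCA4, RCA, RWP1, ABCB4 and GLT1 have overlaps of at most 4%.

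The plot of principal components set lit-shoot and dark roots apart. The first component held 77.3% of the variance and the second 10.7%. On the first component dark roots lay at -76.8 and -57.6 at 4 days and at -149.2 and -140.4 at 7 days, while the 4 lit-shoot libraries lay between 97.4 and 113.4.

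**Figure D1:**
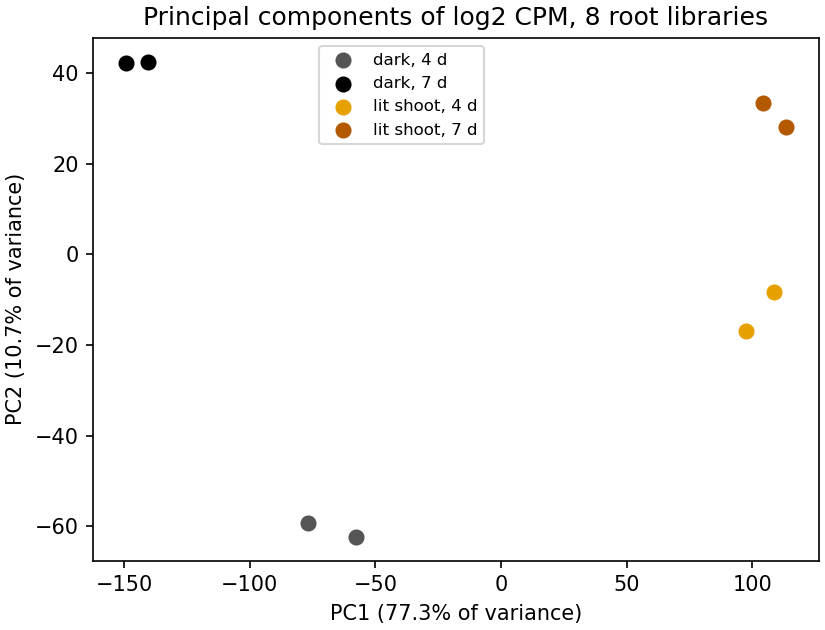
Scores of the 8 root libraries on principal components 1 (77.3% of variance, horizontal) and 2 (10.7%, vertical) of log2 CPM, with each point a library coloured by group. The 4 lit-shoot libraries lie between 97.4 and 113.4 on the horizontal axis and the dark libraries between -149.2 and -57.6.

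The question of the 4-day light comparison was which root transcripts respond when the shoot, and not the root, is lit. Genes of flavonoid, chlorophyll and photosynthesis functions led the rises of named genes, from few or no counts in dark roots. TT4 (AT5G13930, chromosome 5, 4488476 to 4490264, TAIR10.1), which encodes chalcone synthase, rose from 0.125 ± 0.054 to 390 ± 86 CPM (SD, n = 2, log2 fold change 11.55 ± 0.42 SE, edgeR adjusted p = 3.8e-06). G4 (AT3G51820, chromosome 3, 19215930 to 19219128), the chlorophyll synthase gene, had no count in the dark and 8.47 ± 0.56 CPM with lit shoots, at least 135-fold higher (edgeR adjusted p = 1.7e-05). Rises from 1 to 3 counts in the dark libraries were seen for TT5 (AT3G55120, chalcone isomerase, to 39.0 ± 9.8 CPM), F3H (AT3G51240, flavanone hydroxylase, to 89.1 ± 16 CPM), RBCS1A (AT1G67090, small subunit of Rubisco, to 36.1 ± 33 CPM) and CAB1 (AT1G29930, chlorophyll-binding protein, to 35.5 ± 31 CPM). Their 95% counting intervals of the ratio were 333 to 73300, 483 to 6850, 312 to 68700 and 306 to 67500.

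The largest falls of named genes at 4 days were in transcription factor, transporter and jasmonate-related genes. AGL44 (AT2G14210, chromosome 2, 6018558 to 6023863), a MADS-box factor of root development, went from 5.31 ± 2.9 CPM to no count, at least 106-fold lower (edgeR adjusted p = 0.00018). JRG21 (AT3G55970, chromosome 3, 20766735 to 20769410), a jasmonate-regulated gene, fell from 98.7 ± 8.9 to 0.475 ± 0.11 CPM (log2 fold change -7.69 ± 0.26, edgeR adjusted p = 3.7e-06). NAP (AT1G69490, chromosome 1, 26122080 to 26123514), a NAC factor known from leaf senescence, fell from 68.7 ± 8.5 to 0.507 ± 0.037 CPM. FLP1 (AT4G31380, related to flowering-promoting factors) fell from 33.4 ± 6.8 to 0.318 ± 0.3 CPM. The ABC transporter genes ABCC9 (AT3G60160) and ABCC15 (AT3G60970) fell from 20.6 ± 2.9 and 5.76 ± 1.2 CPM to 2 and 3 counts (95% counting intervals of the ratio 169 to 5050 and 38.6 to 557), and as copies of each other their separate values are uncertain.

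Genes of light-dependent metabolism were described by fixed lists. All 11 tested flavonoid genes rose (11 adjusted over the list alone), with a median log2 fold change of 7.47 (camera adjusted p = 3.4e-26, adjusted p = 0.14 with an estimated correlation). CHIL, a chalcone isomerase-like protein, changed by 7.66 ± 0.3 and TT7, a flavonoid hydroxylase, by 5.68 ± 0.37. Nuclear photosynthesis genes rose in 26 of 29 tested members (27 adjusted over the list alone, median 3.99, camera adjusted p = 1.5e-13, adjusted p = 0.36 with an estimated correlation). LHB1B2 (AT2G34420), an antenna protein of photosystem II, went from 0.144 ± 0.14 to 124 ± 44 CPM and PSAF, a photosystem I subunit, from 0.802 ± 0.21 to 20.5 ± 3.7 CPM, while LHCB4.1 had 19.0 ± 1.2 and 18.5 ± 7.4 CPM (edgeR adjusted p = 0.9). Summed over the list, photosynthesis genes held 76.3 CPM in the dark and 645 CPM with lit shoots, beside which the 16 shoot tissue markers held 62 and 41.6 CPM. Of the marker sum, the epidermal gene KCS10 alone held 55.6 and 37 CPM. With lit shoots ATML1, PDF1 and CER1 held 0.768, 0.778 and 2.63 CPM. TMM, SPCH and TGG1 had 20, 4 and 2 counts over both lit-shoot libraries. STM, CLV3, MUTE, FMA, EPF1, EPF2, AFO, YAB3 and TGG2 had 0. Of the 13 tested chlorophyll biosynthesis genes, 7 rose and 4 fell, also adjusted over the list alone (median 0.99, camera adjusted p = 0.0084, adjusted p = 0.43 with an estimated correlation). CRD1, a cyclase subunit, rose by 5.57 ± 0.33 and GUN5, a magnesium chelatase subunit, by 6.2 ± 0.43, whereas GLK2 stood at 0.42 ± 0.31 (edgeR adjusted p = 0.28).

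Carbon starvation, sugar and clock lists went down. Of 27 tested carbon starvation genes, 26 fell and none rose (26 adjusted over the list alone, median -1.91, camera adjusted p = 2e-20, adjusted p = 0.3 with an estimated correlation). DIN9 (AT1G67070, chromosome 1, 25041833 to 25044659), a dark-inducible phosphomannose isomerase, fell from 71.3 ± 6.8 to 9.89 ± 0.25 CPM. BCE2, of branched-chain amino acid breakdown, fell from 587 ± 30 to 67.1 ± 10 CPM, and MGL, methionine gamma-lyase, from 783 ± 1.5 to 68.8 ± 20 CPM. BGAL4 had a log2 fold change of -0.79 ± 0.4 (edgeR adjusted p = 0.13). Sugar transport and cleavage genes fell in 11 and rose in 3 of 16 tested members (11 and 3 adjusted over the list alone, median -1.01, camera adjusted p = 0.0029, adjusted p = 0.3 with an estimated correlation). SWEET2, a vacuolar sugar transporter, fell from 329 ± 5.6 to 65.6 ± 6.2 CPM and the phloem sucrose carrier SUC2 from 82.6 ± 4.7 to 26.6 ± 4.6 CPM, while ATBFRUCT1 did not pass (edgeR adjusted p = 0.092). Clock genes fell in 14 of 22 tested members and rose in 1 (14 and 1 adjusted over the list alone, median -1.18, camera adjusted p = 0.0035, adjusted p = 0.3 with an estimated correlation). LCL1 changed by -1.48 ± 0.15 and PRR7 by -2.11 ± 0.26, and TOC1 by -0.14 (edgeR adjusted p = 0.72).

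Cell cycle, root hair, cytokinin and xylem lists went up at 4 days. All 28 tested cell cycle genes rose (28 adjusted over the list alone, median 1.72, camera adjusted p = 6.9e-15, adjusted p = 0.2 with an estimated correlation). PLE (AT5G51600, chromosome 5, 20960779 to 20964537), a microtubule-binding protein of cytokinesis, rose from 5.35 ± 0.26 to 20.5 ± 0.98 CPM, and PCNA2, the sliding clamp of DNA replication, from 9.3 ± 0.32 to 26.8 ± 0.34 CPM. Root hair genes rose in 18 of 21 tested members (18 rose and 1 fell adjusted over the list alone, median 3.69, camera adjusted p = 9.7e-05, adjusted p = 0.43 with an estimated correlation). The median log2 ratio of this list between replicates 1 and 2 of the dark 4-day group was -1.99. RSL2 (AT4G33880), a basic helix-loop-helix factor of hair growth, rose from 1.36 ± 0.95 to 31.7 ± 0.77 CPM, RHS12 from 0.771 ± 0.75 to 25.1 ± 1.5 CPM, and CSLD3 had -0.27 (edgeR adjusted p = 0.053). Of 15 cytokinin genes 11 rose (12 adjusted over the list alone, median 1.47, camera adjusted p = 0.018, adjusted p = 0.63 with an estimated correlation). The response regulator gene ARR7 rose by 3.83 ± 0.49 and CKX4 by 2.4 ± 0.38. CKX5 did not pass (edgeR adjusted p = 0.68). Dark 4-day replicates 1 and 2 differed by a median log2 ratio of -0.73 in the cytokinin list and -0.53 in the xylem list, and the median absolute log2 ratio of the clock list was 0.75. Xylem and secondary wall genes rose in 11 of 20 tested members (11 adjusted over the list alone, median 0.71, camera adjusted p = 0.018, adjusted p = 0.63 with an estimated correlation). RNS3 rose by 0.71 ± 0.12 and FLA11 by 1.6 ± 0.28. XCP2 stood at 0.51 ± 0.22 (edgeR adjusted p = 0.079).

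Glucosinolate genes went up, and jasmonate and abscisic acid genes went down. Glucosinolate genes rose in 11 of 17 tested members (12 adjusted over the list alone, median 2.76, camera adjusted p = 6e-07, adjusted p = 0.3 with an estimated correlation). The sulfotransferase gene SOT17 rose by 3.16 ± 0.21 and MYB34 from 8.94 ± 2.2 to 60.5 ± 4.4 CPM. MYB51 did not pass (edgeR adjusted p = 0.26). Jasmonate genes fell in 11 of 15 tested members (12 adjusted over the list alone, median -2.73, camera adjusted p = 1.4e-12, adjusted p = 0.3 with an estimated correlation). The repressor genes JAZ7 and JAZ10 fell from 70.1 ± 14 to 2.08 ± 0.028 CPM and from 58.4 ± 4.3 to 1.62 ± 0.034 CPM, while VSP1 had 0.61 (edgeR adjusted p = 0.17). Abscisic acid genes fell in 9 and rose in 1 of 18 tested members (the same numbers adjusted over the list alone, median -0.58, camera adjusted p = 0.011, adjusted p = 0.63 with an estimated correlation). NCED3, a key enzyme of abscisic acid synthesis, fell from 168 ± 15 to 33.9 ± 3.2 CPM and the phosphatase HAI1 from 34.5 ± 11 to 3.06 ± 0.29 CPM. COR47 did not pass (edgeR adjusted p = 0.55). The cytosolic ribosomal protein list rose in 31 and fell in 4 of 46 tested members (31 and 4 adjusted over the list alone, median 0.88, camera adjusted p = 9.7e-05, adjusted p = 0.58 with an estimated correlation). It also held plastid ribosomal proteins and disease resistance genes with the same prefix, such as RPS4, which changed by -1.25 ± 0.1, beside RPL3B at 2.89 ± 0.18.

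In 10 lists the set test did not pass at 4 days. Light signalling genes rose in 6 and fell in 6 of 23 members (5 and 6 adjusted over the list alone), with a median of -0.07 that becomes 0.12 under library totals alone (camera adjusted p = 0.94). The blue light receptor PHOT1 rose by 1.41 ± 0.13 and RUP2 by 1.59 ± 0.24, and PHYA changed by -0.69 ± 0.11. Camera gave adjusted p = 0.41 for auxin (12 up and 4 down of 31), 0.18 for nitrogen (8 and 2 of 17), 0.52 for iron (6 and 2 of 19), 0.5 for root meristem and cap (2 and 2 of 12), 0.95 for Casparian strip and suberin (4 and 3 of 20), and 0.5 for class III peroxidases (18 and 8 of 52). It gave 0.44 for heat shock proteins (0 and 1 of 6), 0.5 for plastid-encoded (21 and 7 of 89) and 0.56 for mitochondrion-encoded genes (14 and 19 of 63, median -0.03, or 0.17 under library totals alone). Within these lists the iron transporter gene IRT1 (AT4G19690, chromosome 4, 10707344 to 10709015) rose from 0.171 ± 0.13 to 44.4 ± 39 CPM, the peroxidase AT1G49570 fell from 53.0 ± 11 to 0.303 ± 0.089 CPM, and ATCG00020 rose from 332 ± 43 to 3150 ± 1400 CPM. HSFA2 changed by -5.38 ± 1.27, and HSP70 had 433 ± 440 CPM in the dark and 141 ± 9 CPM with lit shoots (edgeR adjusted p = 0.1), beside a median log2 ratio of 2.72 for this list between replicates 1 and 2 of the dark 4-day group. Of 4 tested shoot tissue markers, CER1 rose by 2.16 ± 0.56 and KCS10 changed by -0.59 ± 0.12, and the tested seed storage gene CRU3 fell, at least 12-fold.

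Across genes, 6385 were higher and 5559 lower with lit shoots at 4 days, 11944 or 57.1% of those tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With library totals as the only scaling, 7906 were higher and 4043 lower, so that the share of higher calls was 66.2% against 53.5%. Lower calls outnumbered higher ones with a filter of 1 CPM in 2 samples (5800 higher and 6130 lower), with organelle, rRNA and tRNA loci removed (5955 and 6092), and without any single dark library (48.2% to 49.1% higher). That scaling shifted the median log2 fold change of all genes by 0.199 at 4 days and 0.169 at 7 days. The xylem call ended without dark 4-day replicate 1 (camera adjusted p = 0.062), while the heat shock and peroxidase lists passed without dark 4-day replicate 2 (3e-04 and 0.037). The calls of CER1 and HSFA2 ended without lit-shoot 4-day replicate 2 (edgeR adjusted p = 0.062 and 0.064), that of CER1 also without dark 4-day replicate 2 (0.055). Without either lit-shoot 7-day library XCP2 (0.0072 and 0.0071), VSP1 (0.039 and 0.022), MYB51 (0.016) and CSLD3 (0.04) passed, and without either dark 7-day library BGAL4 (0.0045 and 0.0047) and CSLD3 (0.026). Without dark 4-day replicate 2 HSP70 (0.00037) and CSLD3 (0.035) passed, and without lit-shoot 4-day replicate 1 LHCB4.1 (0.045). HSP70 (9e-26), BGAL4 (4.7e-07), MYB51 (2.8e-06), XCP2 (0.00071) and VSP1 (0.013) passed without a filter, XCP2 (0.049) and CSLD3 (0.034) with DESeq2, and CSLD3 with its size factors (0.048).

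**Figure D2:**
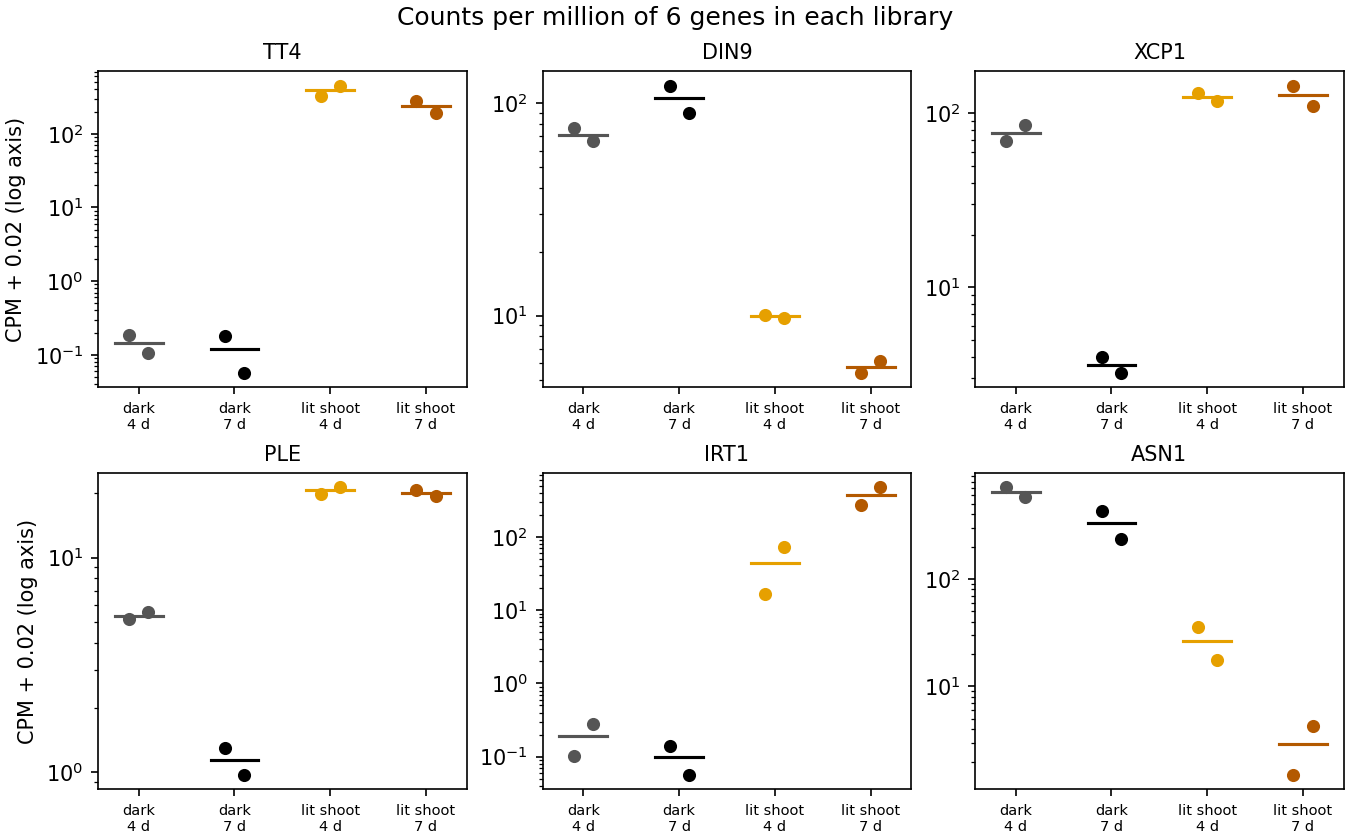
CPM of TT4, DIN9, XCP1, PLE, IRT1 and ASN1 (vertical, log axis, with 0.02 CPM added) in each library of the 4 groups (horizontal), with points for the libraries and a bar for the mean of n = 2. TT4 means are 0.125 and 0.0981 CPM in the dark against 390 and 236 CPM with lit shoots, and XCP1 is lowest in dark roots at 7 days at 3.57 CPM.

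The same question was asked at 7 days. Cytochrome P450, glucosinolate and nutrient transporter genes then led the rises of named genes, and several had no count in dark roots. CYP716A2 (AT5G36140, chromosome 5, 14212174 to 14213293), a cytochrome P450, reached 47.7 ± 5.9 CPM (n = 2), at least 824-fold higher (edgeR adjusted p = 0.00052). The sulfate transporter gene SULTR3;5 (AT5G19600) reached 31.4 ± 5.2 CPM, at least 541-fold higher. From the methionine-derived glucosinolate pathway, CYP83A1 (AT4G13770), CYP79F2 (AT1G16400) and MAM1 (AT5G23010) reached 34.3 ± 25, 27.8 ± 6.4 and 24.2 ± 19 CPM, at least 627-fold, 491-fold and 443-fold higher. IRT1 rose from 0.0782 ± 0.059 to 375 ± 140 CPM (log2 fold change 12.17 ± 1.22, edgeR adjusted p = 0.00016).

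JRG21 led the falls at 7 days, from 483 ± 120 to 0.2 ± 0.027 CPM (log2 fold change -11.22 ± 0.3, edgeR adjusted p = 2.3e-07). THA1 (AT1G08630, chromosome 1, 2743761 to 2747967), a threonine aldolase gene, fell from 293 ± 110 to 0.345 ± 0.23 CPM, NAP from 143 ± 43 to 0.471 ± 0.1 CPM and AGL44 from 33.5 ± 3.4 to 0.118 ± 0.039 CPM. SOM (AT1G03790), a zinc finger regulator of germination, went from 24.3 ± 4.6 CPM to 3 counts (95% counting interval of the ratio 167 to 2370), and DDF1 (AT1G12610), an AP2-type factor, from 6.2 ± 1.2 CPM to 1 count (66.6 to 14800).

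Cell division and xylem lists were far above the dark level at 7 days. All 28 cell cycle genes rose (28 adjusted over the list alone, median 3.11, camera adjusted p = 2e-22, adjusted p = 0.16 with an estimated correlation). PLE changed by 4.17 ± 0.18 and SYP111, a cytokinesis syntaxin, by 4.01 ± 0.19. Xylem and secondary wall genes rose in 19 and fell in 1 of 20 tested members (19 and 1 adjusted over the list alone, median 4.63, camera adjusted p = 3.4e-13, adjusted p = 0.26 with an estimated correlation). XCP1 (AT4G35350, chromosome 4, 16810482 to 16812077), a cysteine peptidase of dying xylem cells, rose from 3.57 ± 0.53 to 127 ± 24 CPM and CTL2 (AT3G16920), a chitinase-like wall protein, from 0.735 ± 0.26 to 46.9 ± 7.3 CPM. Of 21 root hair genes 20 rose (20 adjusted over the list alone, median 6.23, camera adjusted p = 9.1e-05, adjusted p = 0.48 with an estimated correlation). RHD2, an NADPH oxidase, rose by 1.33 ± 0.1 and RSL1 by 4.06 ± 0.39. CSLD3 did not pass (edgeR adjusted p = 0.51). Peroxidases rose in 30 and fell in 6 of 52 tested members (31 and 6 adjusted over the list alone, median 1.04, camera adjusted p = 0.0065, adjusted p = 0.48 with an estimated correlation). AT2G38390 rose from 0.642 ± 0.29 to 75.4 ± 0.69 CPM, AT1G49570 changed by -3.77 ± 0.28, and DOX1 did not pass (edgeR adjusted p = 0.74). Ribosomal proteins rose in 33 and fell in 5 of 46 tested members of the mixed list (33 and 5 adjusted over the list alone, median 0.96, camera adjusted p = 0.00025, adjusted p = 0.55 with an estimated correlation). RPS28 changed by 2.39 ± 0.16. The resistance gene RPS2 stood at -1.8 ± 0.11.

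Flavonoid genes rose in 11 of 11 tested members again (11 adjusted over the list alone, median 7.2, camera adjusted p = 7.2e-14, adjusted p = 0.16 with an estimated correlation). TT4 changed by 11.2 ± 0.42 and RHM1, a rhamnose synthase, by 2.35 ± 0.12. Nuclear photosynthesis genes rose in 23 and fell in 2 of 29 (23 and 2 adjusted over the list alone, median 3.33, camera adjusted p = 0.0011, adjusted p = 0.59 with an estimated correlation). LHB1B2 changed by 8.36 ± 0.52 and PSAF by 3.33 ± 0.28. RCA stood at 0.42 (edgeR adjusted p = 0.34). The list summed to 110 CPM in the dark and 244 CPM with lit shoots, and the shoot tissue markers to 51.6 and 62.5 CPM, of which KCS10 held 49 and 43.4 CPM. Carbon starvation genes fell in all 27 tested members (27 adjusted over the list alone, median -2.78, camera adjusted p = 7.4e-20, adjusted p = 0.26 with an estimated correlation). DIN9 went from 106 ± 22 to 5.72 ± 0.51 CPM and BCE2 from 704 ± 170 to 29.5 ± 4.2 CPM. Clock genes fell in 16 and rose in 1 of 22 (16 and 1 adjusted over the list alone, median -1.83, camera adjusted p = 0.00049, adjusted p = 0.26 with an estimated correlation). BOA changed by -2.76 ± 0.27 and PRR7 by -2.72 ± 0.26. TOC1 did not pass (edgeR adjusted p = 0.2). Nitrogen genes rose in 11 and fell in 2 of 17 tested members (11 and 2 adjusted over the list alone, median 0.95, camera adjusted p = 0.017, adjusted p = 0.48 with an estimated correlation). Nitrate reductase NIA1 went from 5.98 ± 0.5 to 43.9 ± 1 CPM.

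Glucosinolate genes rose in 15 of 17 tested members (15 adjusted over the list alone, median 3.63, camera adjusted p = 1.5e-07, adjusted p = 0.26 with an estimated correlation). SOT17 changed by 3.58 ± 0.2 and the lyase SUR1 by 2.21 ± 0.14. MYB51 did not pass (edgeR adjusted p = 0.46). Jasmonate genes fell in 11 and rose in 2 of 15 (11 and 2 adjusted over the list alone, median -1.97, camera adjusted p = 0.00013, adjusted p = 0.48 with an estimated correlation). JAZ10 fell from 16.1 ± 1.8 to 0.726 ± 0.26 CPM, while VSP1, a storage protein gene, rose from 0.598 ± 0.17 to 35.9 ± 18 CPM. Lit-shoot 7-day replicates 1 and 2 were apart by a median log2 ratio of 0.8 in the jasmonate list, and by a median absolute log2 ratio of 0.87 in the clock list. Abscisic acid genes fell in 12 and rose in 4 of 18 (12 and 4 adjusted over the list alone, median -1.14, camera adjusted p = 0.0054, adjusted p = 0.56 with an estimated correlation). NCED3 changed by -3.22 ± 0.16. COR47 did not pass (edgeR adjusted p = 0.9). Auxin genes rose in 18 and fell in 7 of 31 (18 and 7 adjusted over the list alone, median 0.89, camera adjusted p = 0.0496, adjusted p = 0.59 with an estimated correlation). The repressor gene AXR3 rose from 11.7 ± 3 to 78.7 ± 1.8 CPM. EIR1 did not pass (edgeR adjusted p = 0.69).

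Iron genes rose in 13 and fell in 2 of 19 tested members at 7 days (13 and 2 adjusted over the list alone), with a median of 3.76, or 3.45 with genes at 0 set to their bounds, and the set test did not pass (camera adjusted p = 0.0504, adjusted p = 0.48 with an estimated correlation). NAS1, nicotianamine synthase, rose by 3.76 ± 0.43 and the iron transporter gene IRT2 from no count to 10.2 ± 0.14 CPM, at least 178-fold. Between the lit-shoot libraries of that day, bHLH38 stood at 74.5 and 4.76 CPM and the ferritin gene FER1 at 22.4 and 197 CPM. Camera gave adjusted p = 0.095 for light signalling (4 up and 13 down of 23), 0.28 for chlorophyll (6 and 4 of 13), 0.11 for cytokinin (11 and 2 of 15), 0.23 for sugar (4 and 9 of 16), 0.28 for root meristem and cap (1 and 4 of 12), and 0.23 for Casparian strip and suberin (9 and 2 of 20). It gave 0.21 for heat shock proteins (0 and 5 of 6), 0.28 for mitochondrion-encoded (22 and 6 of 63) and 0.95 for plastid-encoded genes (22 and 20 of 89, where the median of 0.02 and the downward test differ in sign). ARR7 rose by 5.73 ± 0.52, the sucrose carrier SUC1 by 3.27 ± 0.23 and G4 by 5.89 ± 0.32. HSP101 changed by -2.81 ± 0.85. Among 4 tested shoot tissue markers 2 rose, of which PDF1, an epidermal gene, went from 0.0782 ± 0.059 to 12.6 ± 2.4 CPM, and CRU3 fell, at least 2.71-fold.

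At 7 days 7581 genes were higher and 6873 lower, 14454 or 69% of those tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With library totals as the only scaling 8550 were higher and 5719 lower, a share of higher calls of 59.9% against 52.4%. The auxin call ended without dark 7-day replicate 1 (camera adjusted p = 0.12), without lit-shoot 7-day replicate 1 (0.068) and with a replicate block (0.056). The iron list passed with a replicate block (0.0065), without a filter (0.013) and without any single library but lit-shoot 7-day replicate 1, at 0.00015 without replicate 2. Single left-out libraries or no filter also brought past the threshold the cytokinin list (0.011 without a filter, 0.039 and 0.04 without dark 4-day replicates 1 and 2, 0.044 without lit-shoot 7-day replicate 2), the heat shock list (0.0067 and 0.019 without dark 4-day replicates 1 and 2) and the light signalling list (0.039 without lit-shoot 7-day replicate 2, 0.032 without a filter). The calls of HSP101 and HSP70 ended without dark 7-day replicate 1 or either lit-shoot 7-day library (edgeR adjusted p from 0.082 to 0.16), HSFA2's without either of the latter (0.097 and 0.1), and CRU3's without any dark library or either lit-shoot 7-day library (0.06 to 0.12). CRU3 also lost it with a replicate block (0.058) and without a filter (0.082). TOC1 and MYB51 passed without lit-shoot 7-day replicate 1, and both of them and RCA without a filter.

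Light responses at the 2 days shared no library and were compared over the 20936 genes. Genes higher at both days numbered 5368 against 2312 for independent lists (Fisher's exact test, odds ratio 29.4, 95% interval 27.1 to 31.9), and genes lower at both numbered 4822 against 1825 (odds ratio 42.5, 38.8 to 46.6). TT4, JRG21, NAP, DIN9 and JAZ10 were in these overlaps, as were all 11 flavonoid and all 28 cell cycle genes. A further 119 genes were called in opposite directions, 1635 at 4 days alone and 4145 at 7 days alone. Log2 fold changes correlated at 0.81 across genes, which are not independent replicates. Over the genes called in the same direction at both days, their median size was 1.05 at 4 days and 1.38 at 7 days.

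**Figure D3:**
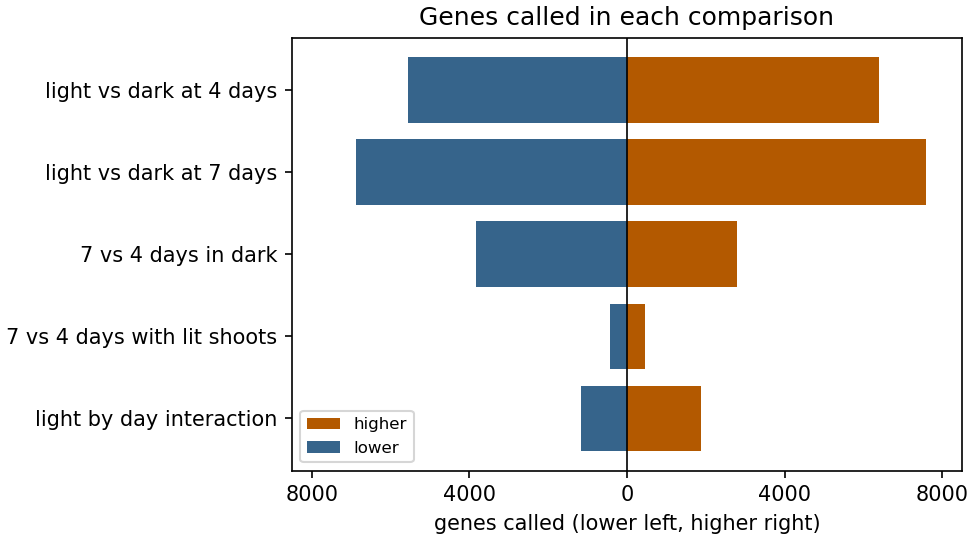
Number of genes called in each comparison (vertical) at an edgeR adjusted p below 0.05, with lower genes to the left of 0 and higher genes to the right (horizontal, number of genes). Bars run from 446 higher and 440 lower for 7 against 4 days with lit shoots to 7581 higher and 6873 lower for light at 7 days.

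The comparison of 7 with 4 days in the dark asked how roots changed while the shoot stayed unlit. Xylem and cell cycle genes went down. All of the 28 cell cycle genes fell (28 adjusted over the list alone, median -1.63, camera adjusted p = 4.6e-22, adjusted p = 0.13 with an estimated correlation). PLE went from 5.35 ± 0.26 to 1.12 ± 0.23 CPM (n = 2) and SYP111 by -2.32 ± 0.2. Xylem and secondary wall genes fell in 19 and rose in 1 of 20 (19 and 1 adjusted over the list alone, median -3.58, camera adjusted p = 1.5e-34, adjusted p = 0.13 with an estimated correlation). XCP1 went from 77.5 ± 12 to 3.57 ± 0.53 CPM (edgeR adjusted p = 1.9e-05) and CTL2 from 18.3 ± 3.3 to 0.735 ± 0.26 CPM. The cellulase gene CEL5 (AT1G22880, chromosome 1, 8095449 to 8097790) went from 10.8 ± 5.4 CPM to 2 counts (95% counting interval of the ratio 76.5 to 2300), and AGP30 (AT2G33790), an arabinogalactan protein of root walls, from 10.8 ± 0.57 to 0.0997 ± 0.14 CPM.

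TBL41, an O-acetyltransferase-like gene, IRT2 and FLA13 (AT5G44130), a fasciclin-like protein, went to no count, at least 10.2-fold, 7.67-fold and 59.2-fold lower, and XTH17 (AT1G65310), a wall-modifying enzyme, went from 10.9 ± 13 CPM to 3 counts (95% counting interval of the ratio 66.1 to 945). Rises were led by CYP82C2 (AT4G31970, chromosome 4, 15462350 to 15464563), a cytochrome P450, from 1.8 ± 0.76 to 64.5 ± 45 CPM (log2 fold change 5.17 ± 0.68, edgeR adjusted p = 0.0029). CEP1 (AT5G50260), a papain-type protease, rose from 1.14 ± 0.63 to 26.7 ± 12 CPM and SRO3 (AT1G70440) from 2.76 ± 0.47 to 24.3 ± 8.6 CPM. GLIP1, a lipase-like gene, and GLP9, a germin-like gene, rose by 3.85 ± 1.2 and 3.51 ± 1.03, and G4 at least 2.13-fold.

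Further lists fell in the dark with time. Root hair genes fell in 10 of 21 (13 adjusted over the list alone, median -2.19, camera adjusted p = 5e-05, adjusted p = 0.54 with an estimated correlation). RHD2 changed by -1.27 ± 0.1. SCN1 did not pass (edgeR adjusted p = 0.34). Dark 4-day replicates differed in this list by a log2 ratio of -1.99. Casparian strip and suberin genes fell in 10 of 20 (13 adjusted over the list alone, median -0.5, camera adjusted p = 5.2e-07, adjusted p = 0.54 with an estimated correlation). Dark 4-day replicates 1 and 2 were apart by a median log2 ratio of -0.35 in this list, 0.49 in the jasmonate list, 0.23 in the clock list (median absolute log2 ratio 0.75) and 0.32 in the mitochondrion-encoded list. CASP5, a scaffold of the Casparian strip, went from 48.6 ± 10 to 4.83 ± 0.11 CPM. RWP1 did not pass (edgeR adjusted p = 0.33). Peroxidases fell in 27 and rose in 1 of 52 (28 and 3 adjusted over the list alone, median -0.98, camera adjusted p = 1e-06, adjusted p = 0.36 with an estimated correlation). AT2G38390 changed by -3.92 ± 0.23. AT5G19890 rose from 0.252 ± 0.011 to 8.8 ± 0.012 CPM. Auxin genes fell in 13 of 31 (15 adjusted over the list alone, median -0.74, camera adjusted p = 0.00019, adjusted p = 0.54 with an estimated correlation). AXR3 changed by -1.69 ± 0.16 and the efflux carrier gene PIN7 by -1.17 ± 0.13. ABCB4 did not pass (edgeR adjusted p = 0.45). Jasmonate genes fell in 9 of 15 (10 adjusted over the list alone, median -1.06, camera adjusted p = 0.00019, adjusted p = 0.58 with an estimated correlation). JAZ10 changed by -1.86 ± 0.16. JAZ1 did not pass (edgeR adjusted p = 0.052). Nitrogen genes fell in 7 of 17 (8 adjusted over the list alone, median -0.44, camera adjusted p = 0.0072, adjusted p = 0.54 with an estimated correlation). NIA1 changed by -2.12 ± 0.2. GLT1 did not pass (edgeR adjusted p = 0.9).

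Clock genes rose in 6 of 22 (3 adjusted over the list alone, median 0.49, camera adjusted p = 0.0072, adjusted p = 0.36 with an estimated correlation). RVE1 changed by 1.64 ± 0.35, which did not hold without dark 4-day replicate 2 (edgeR adjusted p = 0.053). The mixed ribosomal list fell in 18 and rose in 2 of 46 (21 and 4 adjusted over the list alone, median -0.36, camera adjusted p = 0.031, adjusted p = 0.82 with an estimated correlation). RPL10B changed by -1.31 ± 0.18. Mitochondrion-encoded genes fell in 21 and rose in 1 of 63, also adjusted over the list alone (median -0.5, camera adjusted p = 0.0052, adjusted p = 0.58 with an estimated correlation). The mitochondrial share of counts was 9.57 ± 1.3% at 4 and 4.84 ± 0.35% at 7 days, or 1.54 ± 0.23% and 1.09 ± 0.033% with the 2 most abundant loci left out. Camera gave adjusted p = 0.1 for light signalling (3 up and 1 down), 0.69 for flavonoid (0 and 2), 0.49 for photosynthesis (3 and 0, median 0.02, or 0.00 without organelle, rRNA and tRNA loci), 0.37 for chlorophyll (3 and 0), 0.49 for cytokinin (2 and 2), 0.23 for carbon starvation (4 and 1), 0.1 for sugar (1 and 6) and 0.48 for iron genes (0 and 1). It gave 0.36 for root meristem and cap (0 and 4), 0.75 for abscisic acid (3 and 3), 0.13 for heat shock (1 and 0, beside the replicate ratio of 2.72 in the dark 4-day group), 0.84 for glucosinolate (1 and 2) and 0.12 for plastid-encoded genes (14 and 2). In cytokinin, chlorophyll and glucosinolate the median (-0.18, 0.00 and -0.06) and the test differed in sign or the median was 0. Of the 4 shoot tissue markers PDF1 fell, by -3.29 ± 0.79, and CRU3 did not pass.

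In all, 2788 genes were higher and 3836 lower at 7 days in the dark, 6624 or 31.6% of those tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With library totals as the only scaling 3386 were higher and 3355 lower, a share of higher calls of 50.2% against 42.1%. The calls numbered 3910 (1189 higher and 2721 lower) without dark 4-day replicate 2, 3487 (1122 and 2365) without dark 7-day replicate 1 and 4634 (1584 and 3050) without dark 4-day replicate 1. The ribosomal call ended without the first or the second of these (camera adjusted p = 0.12 and 0.099) and the mitochondrial call without dark 4-day replicate 1 (0.16). Without dark 4-day replicate 1 the heat shock list passed (1.4e-07), without dark 7-day replicate 2 the carbon starvation (0.0076) and plastid-encoded lists (0.006), and without dark 7-day replicate 1 light signalling (0.042). The calls of FLA13 and GLIP1 ended without 6 libraries each (edgeR adjusted p from 0.061 to 0.12 for FLA13, which lost it without any library but the dark 4-day ones, and from 0.069 to 0.21 for GLIP1, which lost it without any but the lit-shoot 7-day ones). GLP9 lost its call without any library but dark 7-day replicate 1 (0.069 to 0.18), XTH17 without any 7-day library (0.063 to 0.12), G4 without either dark 4-day library (0.084) and PDF1 without dark 4-day replicate 1 or dark 7-day replicate 2 (0.078 and 0.083). A replicate block also ended the calls of FLA13 (0.062) and GLIP1 (0.06), and DESeq2 size factors that of GLIP1 (0.052). JAZ1 passed without either lit-shoot 7-day library, without a filter, with a replicate block (0.024) and with DESeq2 (0.0061).

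The comparison of 7 with 4 days under lit shoots asked how the roots changed with age under that condition. By the set test glucosinolate genes went up and photosynthesis and carbon starvation genes down, with 5 of 17, 5 of 29 and 8 of 27 members called and adjusted p = 0.1, 0.41 and 0.41 with an estimated correlation. BCAT4 (AT3G19710, chromosome 3, 6846969 to 6849582), of methionine chain elongation, rose from 0.834 ± 0.47 to 54.9 ± 48 CPM (n = 2, log2 fold change 6.04 ± 0.87, edgeR adjusted p = 0.024), CYP82C2 from 4.05 ± 1.2 to 201 ± 58 CPM and CYP83A1 from 1.23 ± 0.93 to 34.3 ± 25 CPM. GLR2.2 (AT2G24720), a glutamate receptor-like channel gene, rose from 0.812 ± 0.065 to 13.0 ± 2.3 CPM, AK3 (AT3G02020), an aspartate kinase gene, from 0.871 ± 0.81 to 22.6 ± 16 CPM, and ABCC9 from 2 counts to 0.847 ± 0.091 CPM (95% counting interval of the ratio 6.54 to 211). ICL (AT3G21720, chromosome 3, 7652487 to 7656053), isocitrate lyase of the glyoxylate cycle, fell from 48.8 ± 13 to 5 ± 0.12 CPM (-3.28 ± 0.39, edgeR adjusted p = 0.012), THA1 from 6.62 ± 4.4 to 0.345 ± 0.23 CPM, and ASN1 (AT3G47340), a dark-inducible asparagine synthase, from 26.7 ± 13 to 2.88 ± 2 CPM. CAB1, HOL2 (AT2G43920), a methyltransferase gene, and RRTF1 (AT4G34410), a redox-responsive factor, changed by -3.87 ± 0.69, -3.79 ± 0.73 and -3.45 ± 0.64.

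Glucosinolate genes rose in 5 of 17 (14 adjusted over the list alone, median 1.12, camera adjusted p = 2.8e-13, adjusted p = 0.1 with an estimated correlation). SOT17 changed by 1.13 ± 0.18 and IMS2 by 2.84 ± 0.5. CYP83B1 did not pass (edgeR adjusted p = 0.25). No iron gene was called over all genes, and 6 rose adjusted over the list alone (median 1.55, camera adjusted p = 2.7e-07, adjusted p = 0.1 with an estimated correlation). In the 7-day replicates bHLH38 stood at 74.5 and 4.76 CPM. Photosynthesis genes fell in 5 of 29 (25 adjusted over the list alone, median -1.48, camera adjusted p = 2.4e-15, adjusted p = 0.41 with an estimated correlation). LHB1B2 went from 124 ± 44 to 32.9 ± 7 CPM. LHCA4 did not pass (edgeR adjusted p = 0.073). Shoot tissue markers summed to 41.6 and 62.5 CPM at 4 and 7 days, with KCS10 at 37 and 43.4 CPM. Carbon starvation genes fell in 8 of 27 (18 adjusted over the list alone, median -0.65, camera adjusted p = 1.2e-12, adjusted p = 0.41 with an estimated correlation). The proline dehydrogenase gene ERD5 fell from 479 ± 64 to 197 ± 46 CPM. DIN2 did not pass (edgeR adjusted p = 0.67). Flavonoid genes fell in 2 and rose in 1 of 11 (6 and 1 adjusted over the list alone, median -0.72, camera adjusted p = 7.3e-05, adjusted p = 0.41 with an estimated correlation). TT7 changed by -2.26 ± 0.28. Casparian strip and suberin genes fell in 4 of 20 (7 adjusted over the list alone, median -0.48, camera adjusted p = 6.5e-07, adjusted p = 0.41 with an estimated correlation). CASP5 went from 49.9 ± 5.9 to 14.9 ± 0.83 CPM. Root meristem and cap genes fell in 3 of 12 (6 adjusted over the list alone, median -0.63, camera adjusted p = 0.00075, adjusted p = 0.47 with an estimated correlation). AIL6 changed by -0.85 ± 0.15. Replicates 1 and 2 of the lit-shoot 7-day group were apart by a median log2 ratio of -0.46 in this list, -0.59 in photosynthesis, 0.32 in Casparian strip and -0.42 in root hair genes. Those of the lit-shoot 4-day group were apart by 0.84 in photosynthesis, 0.37 in carbon starvation, -0.36 in flavonoid and 0.24 in Casparian strip genes.

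Camera also called 4 lists downward that did not hold when lit-shoot libraries were left out. Light signalling (0 up and 1 down, the same adjusted over the list alone) had camera adjusted p = 0.02, adjusted p = 0.41 with an estimated correlation and 0.086 without 4-day replicate 1. Others were chlorophyll (0 and 0, or 0 and 1 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.47 with an estimated correlation, 0.072 without 4-day replicate 1), abscisic acid (0 and 3, or 0 and 6 adjusted over the list alone, camera adjusted p = 0.0091, adjusted p = 0.78 with an estimated correlation, 0.11 without 7-day replicate 1) and root hair (0 and 1, the same adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.88 with an estimated correlation). The root hair value was 0.052 and 0.06 without 4-day replicates 1 and 2 and 0.21 without 7-day replicate 1. Adjusted p was 0.97 for clock (0 called, median -0.01), 0.08 for auxin (0), 0.37 for cytokinin (0), 0.97 for nitrogen (0, median -0.02), 0.27 for cell cycle (0), 0.5 for xylem (0 up and 2 down, median -0.03), 0.25 for jasmonate (1 and 1) and 0.56 for heat shock genes (0). It was 0.95 for sugar (2 and 1, median -0.08 and test up), 0.95 for peroxidases (3 and 3), 0.32 for ribosomal (0 and 1), 0.64 for plastid-encoded (2 and 0, median -0.01 and test up) and 0.98 for mitochondrion-encoded genes (2 and 3, median 0.02 and test down). The medians of the clock, nitrogen, xylem and plastid-encoded lists changed sign under another scaling. PDF1 was the called shoot tissue marker, at 4.01 ± 0.45 higher, and CRU3 did not pass.

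Only 886 genes were called, 446 higher and 440 lower, or 4.2% of those tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), against 4531 at an unadjusted p under 0.05. DESeq2 called 771 higher and 1000 lower, while edgeR called 494 and 364 with organelle, rRNA and tRNA loci removed, 495 and 382 with a filter of 1 CPM in 2 samples, and 428 and 336 with only the 4 samples compared. Without lit-shoot 4-day replicate 1 edgeR called 0 genes (2716 at an unadjusted p under 0.05, lowest adjusted p 0.065, 482 called by DESeq2 and 10 by limma-voom), so that every gene call named here for this comparison ended, and without lit-shoot 4-day replicate 2 or 7-day replicate 1 it called 108 and 354. Single left-out libraries or, for auxin, no filter brought past the threshold the lists of auxin (0.047 without a filter, 0.033 without dark 7-day replicate 1, dark 7-day replicate 2 or lit-shoot 7-day replicate 1), heat shock (0.049 without dark 4-day replicate 2), jasmonate and xylem (camera adjusted p = 0.00047 and 0.033 without lit-shoot 7-day replicate 1), ribosomal (0.0032 without lit-shoot 7-day replicate 2) and plastid-encoded genes (0.013 without lit-shoot 4-day replicate 1, 0.047 without lit-shoot 7-day replicate 1). LHCA4 passed without lit-shoot 7-day replicate 2 and with DESeq2 (adjusted p = 0.0087), and LHCA4 and CYP83B1 without a filter. A replicate block ended the call of ASN1 (edgeR adjusted p = 0.057).

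**Figure D4:**
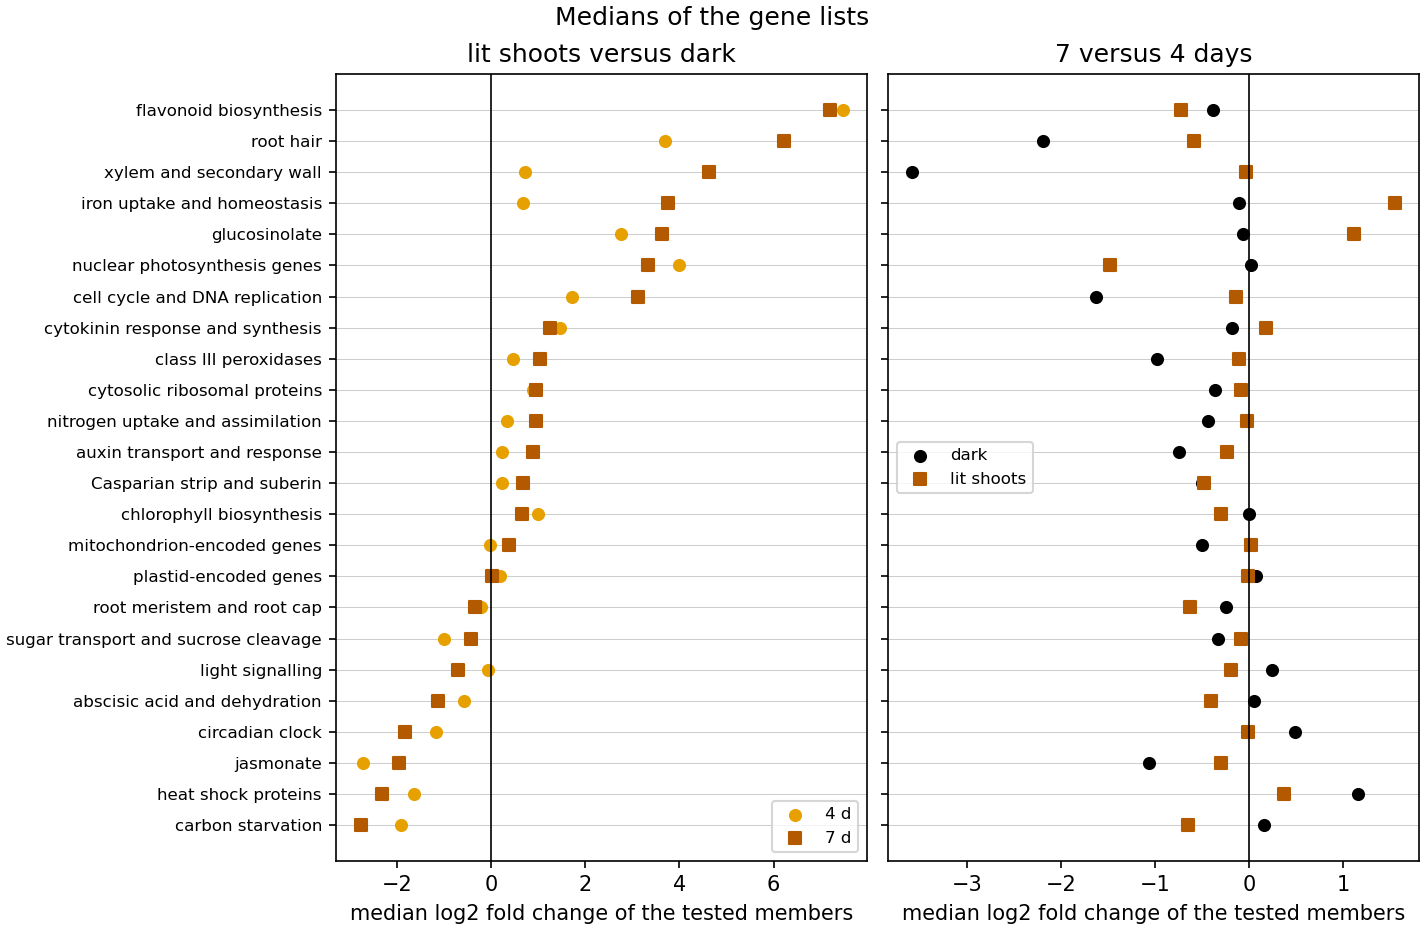
Median log2 fold change of the tested members (horizontal) of 24 gene lists (vertical) for lit shoots against dark at 4 and 7 days (left) and for 7 against 4 days in the dark and with lit shoots (right), with a point for each list and comparison. Xylem and secondary wall genes lie at 0.71 and 4.63 on the left and at -3.58 and -0.03 on the right, where the last value changes sign under another scaling.

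The interaction tested whether the effect of shoot light differed between 7 and 4 days. Differences are given as the log2 light effect at 7 days minus that at 4 days. They were mostly positive in xylem and cell cycle genes. Of 20 xylem and secondary wall genes 17 had a positive and 1 a negative difference (18 and 1 adjusted over the list alone, median 3.43, camera adjusted p = 3.1e-36, adjusted p = 0.13 with an estimated correlation). XCP1 changed by 4.46 ± 0.25 (edgeR adjusted p = 0.00012) and CTL2 by 4.98 ± 0.33. The laccase gene LAC17 changed by 4.24 ± 0.33. GUT2 did not pass (edgeR adjusted p = 0.16). Cell cycle genes had a positive one in 24 of 28 (26 adjusted over the list alone, median 1.5, camera adjusted p = 2.5e-20, adjusted p = 0.13 with an estimated correlation). PLE changed by 2.23 ± 0.24. CDT1A stood at 0.4 (edgeR adjusted p = 0.3). DJ1F (AT3G54600), a class I glutamine amidotransferase-like gene, had 1.22 ± 0.81 and 3.4 ± 0.53 CPM at 4 days and 1 count and 16.5 ± 5.5 CPM at 7 days in dark and lit order, a difference of 7.98 ± 1.03. ICS2 (AT1G18870), an isochorismate synthase gene, had 0.823 ± 0.24 and 12.4 ± 1.1 CPM, then 1 count and 48.5 ± 14 CPM (7.08 ± 0.81). Differences of CEL5 and IRT2 were 6.88 ± 0.89 and 7.18 ± 1.34, and all 4 are fitted values that rest on 0 to 2 counts in dark roots at 7 days and are no bounds.

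Negative differences were led by HOL2 (-5.36 ± 0.85), THA1 (-5.15 ± 0.9), G4 (-4.97 ± 1.16, with no count in 1 group) and ICL (-4.22 ± 0.52, edgeR adjusted p = 0.0039). ICL had 713 ± 370 and 48.8 ± 13 CPM at 4 days against 1370 ± 100 and 5 ± 0.12 CPM at 7 days in dark and lit order. Carbon starvation genes, of which 26 and 27 fell with light at 4 and 7 days, had a negative difference in 10 of 27 (15 adjusted over the list alone, median -0.85, camera adjusted p = 4e-08, adjusted p = 0.49 with an estimated correlation). DIN9 changed by -1.36 ± 0.22. Photosynthesis genes had it in 4 of 29, also adjusted over the list alone (median -1.32, camera adjusted p = 0.00033, adjusted p = 0.52 with an estimated correlation). Light signalling genes had it in 3 of 23, also adjusted over the list alone (median -0.43, camera adjusted p = 0.0026, adjusted p = 0.22 with an estimated correlation). RUP1 changed by -1.77 ± 0.31. Clock genes had it in 1 of 22 (0 adjusted over the list alone, median -0.61, camera adjusted p = 0.0076, adjusted p = 0.22 with an estimated correlation).

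Positive differences were found in 14 of 52 peroxidases (16 adjusted over the list alone, median 0.77, camera adjusted p = 9.3e-07, adjusted p = 0.22 with an estimated correlation). AT2G38390 changed by 4.18 ± 0.28. They were found in 3 of 19 iron genes, also adjusted over the list alone (median 1.88, camera adjusted p = 0.0026, adjusted p = 0.22 with an estimated correlation). There bHLH38 stood at 74.5 and 4.76 CPM in the lit-shoot 7-day replicates. For root hair, with the dark 4-day replicates apart by -1.99, they were 3 of 21 (4 adjusted over the list alone, median 1.99, camera adjusted p = 0.0032, adjusted p = 0.52 with an estimated correlation). For glucosinolate they were 3 of 17 (5 adjusted over the list alone, median 0.98, camera adjusted p = 0.0053, adjusted p = 0.49 with an estimated correlation). For auxin they were 6 of 31 (9 adjusted over the list alone, median 0.4, camera adjusted p = 0.011, adjusted p = 0.52 with an estimated correlation). AXR3 differed by 1.29 ± 0.21. Nitrogen had 3 of 17 (7 adjusted over the list alone, median 0.47, camera adjusted p = 0.011, adjusted p = 0.49 with an estimated correlation). NIA1 stood at 2.75 ± 0.27. Mitochondrion-encoded genes had 10 of 63, also adjusted over the list alone (median 0.46, camera adjusted p = 0.011, adjusted p = 0.52 with an estimated correlation). Mitochondrial shares were 9.57% in the dark and 4.21% with lit shoots at 4 days and 4.84% and 4.56% at 7 days, or 1.54% and 1.09%, then 1.09% and 1.16%, with the 2 most abundant loci left out. Casparian strip and suberin genes had 5 positive and 1 negative of 20 (8 and 1 adjusted over the list alone, median 0.32, camera adjusted p = 0.035, adjusted p = 0.66 with an estimated correlation). Jasmonate genes had 2 of 15, also adjusted over the list alone (median 0.68, camera adjusted p = 0.035, adjusted p = 0.7 with an estimated correlation). VSP1 stood at 5.3 ± 0.55. Replicates of the lit-shoot 7-day group were apart by a median absolute log2 ratio of 0.8 in the jasmonate, 0.87 in the clock and 0.36 in the nitrogen list. Those of the dark 4-day group were apart by 0.41 in the Casparian strip, 0.61 in the glucosinolate and 0.37 in the mitochondrion-encoded list, and those of the dark 7-day group by 0.35 in the auxin list. Camera gave adjusted p = 0.62 for flavonoid (1 positive and 0 negative), 0.0504 for chlorophyll (0 and 1, or 0.041 with a replicate block, 0.048 with DESeq2 size factors and 0.033 without a filter), 0.72 for cytokinin (1 and 1, median 0.08 and test down), 0.086 for sugar (6 and 0), 0.3 for root meristem and cap (0 and 2), 0.086 for abscisic acid (0 and 3), 0.23 for heat shock (0), 0.16 for ribosomal (6 and 2) and 0.17 for plastid-encoded genes (1 and 3). Among sugar genes SUC2 differed by 1.68 ± 0.19, and PDF1 was the called shoot tissue marker at 7.3 ± 0.87.

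The interaction called 1890 genes with a positive and 1167 with a negative difference, 3057 or 14.6% of those tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The positive share was 61.8%, against 56.1% with library totals as the only scaling, 69.7% with a filter of 1 CPM in 2 samples, 71.2% with organelle, rRNA and tRNA loci removed, and up to 77.3% with a library left out (without dark 7-day replicate 1). Of the genes called, 2256 had a larger effect of the same sign at 7 days, 212 a smaller one and 589 opposite signs, while 2571 were also called for time in the dark and 398 for time with lit shoots. It called 832 genes without lit-shoot 4-day replicate 1, 1107 without its replicate 2, 1573 without dark 7-day replicate 1 and 1877 without dark 4-day replicate 2. The jasmonate call ended without dark 4-day replicate 1 (camera adjusted p = 0.44), either dark 7-day replicate (0.058 and 0.096), lit-shoot 4-day replicate 2 (0.074) or lit-shoot 7-day replicate 1 (0.39) and stood at 0.05 without a filter, and the Casparian strip call without dark 4-day replicate 2 (0.1), dark 7-day replicate 2 (0.065), lit-shoot 4-day replicate 2 (0.085) or lit-shoot 7-day replicate 1 (0.38). Without dark 4-day replicate 2 the auxin (0.055), root hair (0.15) and glucosinolate calls (0.055) ended, without dark 7-day replicate 1 auxin (0.07), without dark 4-day replicate 1 mitochondrion-encoded genes (0.2) and without lit-shoot 7-day replicate 1 nitrogen (0.051). The heat shock list passed without dark 4-day replicate 1 (2.6e-06). Chlorophyll passed without any of dark 4-day replicate 2, dark 7-day replicate 1, lit-shoot 4-day replicate 2 and lit-shoot 7-day replicate 2 (0.0051 to 0.044), abscisic acid without any of dark 4-day replicate 1, dark 7-day replicate 2, lit-shoot 4-day replicate 2 and lit-shoot 7-day replicate 2 (0.015 to 0.039). Plastid-encoded genes passed without dark 7-day replicate 2 or lit-shoot 4-day replicate 2 (0.015 and 0.035), ribosomal without lit-shoot 7-day replicate 1 (0.0042) and sugar without lit-shoot 4-day replicate 1 (0.045). G4 lost its call without any library but lit-shoot 7-day replicate 1 (edgeR adjusted p from 0.055 to 0.12), HOL2 without either lit-shoot 7-day replicate (0.053 and 0.075), THA1 without either of these or dark 4-day replicate 2 (0.069, 0.1 and 0.054), and IRT2 without lit-shoot 4-day replicate 1 (0.055). G4 also lost its call with DESeq2 (0.053). GUT2 passed without dark 4-day replicate 1 and without a filter.

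Organelle shares of the counts were compared within each day. Mitochondrial loci held 4.21 ± 0.45% of the counts with lit shoots and 9.57 ± 1.3% in the dark at 4 days (n = 2 each, exact permutation test, two-sided, p = 0.333, the smallest that 2 against 2 allows), and 4.56 ± 2.7% and 4.84 ± 0.35% at 7 days (exact p = 1). Plastid loci held 1.51 ± 0.28% and 0.94 ± 0.042% at 4 days and 1.47 ± 0.025% and 0.907 ± 0.096% at 7 days (exact p = 0.333 for both). The design could not reach a p below 0.333 here. With the 2 most abundant mitochondrial loci left out, a choice made after seeing the data, the shares with lit shoots and in the dark were 1.09 ± 0.033% and 1.54 ± 0.23% at 4 days and 1.16 ± 0.033% and 1.09 ± 0.033% at 7 days, where the sign of the difference turned.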

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

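For the patterns weighed here, the tests of transcript length with GC content, an alternative added after the data were seen, and of scaling on the dark pattern were set before their own results, and the tests of a smaller root tip share, of shoot tissue, of scaling on the photosynthesis genes and of the iron genes were chosen only after the result was seen. The effect of shoot light differed between 4 and 7 days for 3057 genes by the interaction test. Named genes that differed this way (log2, 7 minus 4 days) were DJ1F at 7.98, IRT2 at 7.18, ICS2 at 7.08, CEL5 at 6.88, HOL2 at -5.36, THA1 at -5.15, G4 at -4.97 and ICL at -4.22.

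Lists called by the set test of this difference did not pass with an estimated correlation (lowest adjusted p = 0.13), and 14.6% of all tested genes were called. Their called members numbered 24 of 28 for cell cycle, 18 of 20 for xylem and secondary wall, 14 of 52 for peroxidases, 10 of 27 for carbon starvation and 10 of 63 for mitochondrion-encoded genes. They numbered 6 of 31 for auxin, 6 of 20 for Casparian strip and suberin, 4 of 29 for nuclear photosynthesis, 2 of 15 for jasmonate and 1 of 22 for clock genes. Light signalling (of 23), nitrogen (of 17), iron (of 19), root hair (of 21) and glucosinolate (of 17) had 3 each.

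Much of the difference in cell cycle and xylem genes lay in the dark roots, where 47 members of these lists were lower at 7 than at 4 days. Removing per-library trends in exon length and GC content left 95.7% of those members called lower, which argues against these trends as the whole cause. Scaling was not tested by the gap of their median to that of all genes (-2.14 over 3 other scalings), since a factor per library moves all genes alike. A smaller share of root tip stays open, as the meristem and cap list need not follow it. From 4 to 7 days with lit shoots its median was -0.63 beside -0.14 for cell cycle genes. In the dark its lower quartile was -0.64 and the cell cycle median -1.63, and 4 of its 12 fell and 0 rose. A loss of dividing cells that leaves the list in place would not be seen by this test. The age of the dark-grown seedlings, which the design names, was not tested apart and stays open, as does tissue composition.

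Nuclear photosynthesis genes were higher in roots of lit seedlings, and shoot tissue in the root samples is a candidate source. If it were the only source, the members would keep a common ratio between the lit-shoot libraries at 4 days, and for 19.2% (5 of 26) the 95% counting interval lay wholly outside 1.5 times either side of the pooled ratio of 1.81, from PSBR at 1.08 to RBCS1A at 4.58. The ratio itself lay outside for 8 (30.8%), but the bound for arguing against this source was over 20% by the intervals, so that shoot tissue and expression in the root cannot be told apart by this test. The gap of the list median to that of all genes, at least 3.91 over 3 other scalings, does not test scaling for the same reason. The list median itself was 3.93 to 4.17 under these scalings, which argues against the choice among them as the cause. A response of root cells to shoot light was not tested apart from the device or stray light.

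Iron genes stood apart between the lit-shoot replicates at 7 days. Of 19 members 6 were over 2-fold higher in replicate 1 and 3 over 2-fold higher in replicate 2. This argues against scaling as the whole cause, since a factor per library moves all members alike. Their median absolute log2 ratio of 0.93 reached percentile 100 of 10000 random lists matched on expression, whose 95th percentile was 0.35. That met the bound written against a general difference between the libraries, but 12 of 24 lists reached the 99th percentile in this group, and the reading was changed to undecided after this was seen. A general difference and an iron-specific one thus cannot be told apart. No biological explanation was tested, since both libraries belong to the same group.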

How the results depend on the processing

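Removal of the 2 most abundant mitochondrial loci was a test chosen only after the result was seen, and removal of length and GC trends was added after the data were seen but before its own result. No called named gene reversed with a replicate block, DESeq2 size factors, DESeq2, no filter or a library left out. No called list reversed with a replicate block, DESeq2 size factors, no filter, an estimated correlation or a library left out. The other settings, library totals among them, were not checked for reversal. Calls also at least 2-fold numbered 5975 and 8676 for light at 4 and 7 days, 2873 and 424 for time in the dark and with lit shoots, 1904 for the interaction and 4952 for the overlap. At an adjusted p below 0.01 they were 3118 for time in the dark, 64 with lit shoots and 746 for the interaction. Without a filter they were 3056 with lit shoots and 4964 for the interaction, and DESeq2 called 1771 with lit shoots. The stricter limits give fewer by construction, and for the others the cause was not tested. With an estimated correlation camera called 0 lists in each of the 5 comparisons, against 14, 14, 11, 11 and 15 at the preset one, and fry called 15, 21, 10, 2 and 6. Without the 2 most abundant mitochondrial loci the difference in share was -0.454 percentage points against -5.36 at 4 days and turned to 0.0751 against -0.279 at 7 days.

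With each library left out in turn, calls ran from 8519 to 12120 and from 12551 to 14580 for light at 4 and 7 days, from 3487 (without dark 7-day replicate 1) to 6993 in the dark, from 0 (without lit-shoot 4-day replicate 1) to 1111 with lit shoots, and from 832 (without the same library) to 2918 for the interaction. For the 0, edgeR gave 2716 genes at an unadjusted p under 0.05, DESeq2 called 482 and limma-voom 10. In the dark 3910 were called without dark 4-day replicate 2. With lit shoots 108 and 354 were called without lit-shoot 4-day replicate 2 and 7-day replicate 1. For the interaction 1877, 1573 and 1107 were called without dark 4-day replicate 2, dark 7-day replicate 1 and lit-shoot 4-day replicate 2. Lists called ranged over 13 to 16, 13 to 17, 10 to 13, 10 to 14 and 13 to 17. Named gene calls lost in some setting were 2 of 83, 4 of 86, 27 of 77, 50 of 50 and 37 of 67, of which a replicate block ended 0, 1, 4, 4 and 3. A group left with 1 library was assumed to vary like the others.

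Replicate numbers were not taken as pairs, because the labels give no shared day. Deviations of same-numbered libraries correlated at 0.01 to 0.09. A replicate block gave 11887, 14377, 6627, 965 and 3065 calls and an overlap of 10167. With length and GC trends removed, 11820, 14207, 6268, 725 and 2759 were called. Groups of 2 limit the power, and simulated changes of 1.5-fold were recovered in 7.5%, 10.4%, 7.5%, 11.9% and 0% of genes.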

Other observations

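All tests in this part were chosen only after the result was seen. Because the fixed ribosomal list mixed several kinds of genes, a list of eukaryote-type 40S and 60S ribosomal proteins was rebuilt, with 132 of 144 members tested. With lit shoots 98 rose and 7 fell at 4 days (median log2 fold change 1.1, camera adjusted p = 1.4e-13, adjusted p = 0.5 with an estimated correlation), and 104 rose and 8 fell at 7 days (median 1.6, camera adjusted p = 1.6e-13, adjusted p = 0.45 with an estimated correlation). In the dark 65 fell and 5 rose from 4 to 7 days (median -0.5, camera adjusted p = 9.7e-05, adjusted p = 0.81 with an estimated correlation), and with lit shoots 1 fell (median -0.03, camera adjusted p = 0.95). The interaction called 23 higher and 4 lower (median 0.44, camera adjusted p = 8e-04, adjusted p = 0.66 with an estimated correlation).

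Iron genes of the lit-shoot group at 7 days, named after their values were seen, went in both directions between replicates 1 and 2. The regulator genes BHLH100 and bHLH38 stood at 11.5 and 0.482 CPM and at 74.5 and 4.76 CPM, NAS4 at 47.9 and 4.48 CPM and the transporter gene OPT3 at 177 and 39.5 CPM. FER1 was at 22.4 and 197 CPM, NAS2 at 16.9 and 164 CPM and CYP82C4 at 31.5 and 172 CPM. Mitochondrial shares were 6.46% and 2.66%, with 5.34% and 1.54% in the top 2 loci.

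In the dark 4-day group HSP101 stood at 218.8 CPM in replicate 1 and 30.21 CPM in replicate 2, and HSP70 at 742.9 and 123.9 CPM. The median log2 ratio of replicate 1 to replicate 2 was 2.72 for the heat shock list and -1.99 for the root hair list. Dark 4-day replicate 1 had a count at 25315 loci against 22276 in replicate 2, and 1360 loci had counts in it alone, of which 1216 had at most 3 counts and 624 were pseudogenes. In dark 7-day replicate 1 the loci with counts in it alone numbered 665. Seed storage genes summed to 1.31 and 1.04 CPM in the dark at 4 and 7 days and to 0.455 and 0.13 CPM with lit shoots.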
